A study of Mus musculus with 2 samples.

How the data were processed

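The series holds 2 RNA sequencing libraries of OCCM-30 cells, an immortalized mouse line with properties of cementoblasts, the cells that lay down the mineralized cementum on tooth roots. One library came from cells put under compressive force and the other from control cells. Per the labels' protocols, the cells grew in Dulbecco's modified Eagle's medium with serum, RNA was extracted with Trizol, and libraries followed standard Illumina protocols. The size and duration of the force are not given in the sources used here. The labels name 1 sample per group, so no difference between the libraries has a replicate check.

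The deposited table gives whole-number read counts per gene for both libraries, with a gene symbol and a gene type for each of 44792 rows. HISAT2, a spliced aligner, and the mouse genome build GRCm38 are named in the submitters' processing notes. The counting tool, the annotation version, the strand setting and the treatment of reads with several alignments are not given in the sources used here. The deposited counts carry no normalization. How reads with several alignments were counted decides the values of genes with near-identical copies, such as ribosomal protein genes, histone genes, mitochondrially encoded genes, Gapdh and processed pseudogenes, so ratios of such genes are uncertain. Without a known strand setting, reads of a gene and of an overlapping antisense gene cannot be separated, so ratios of overlapping genes are uncertain too.

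Library totals were 24296292 counts for the compressed library and 25049919 counts for the control library. Trimmed mean of M-values (TMM) factors from edgeR 4.0.16 in R 4.3.3 scaled these totals to effective library sizes, and CPM values were computed from the deposited counts on those sizes. The log2 ratio of the compressed to the control library used a prior count of 0.5. Each ratio has an exact 95% conditional binomial (Clopper-Pearson) interval. Sequenced reads are not independent molecules, so the intervals and floors cover counting error only and leave out the spread between cultures. Where a library had 0 counts, the fold was computed against a floor of 3 counts in that library, equal to 0.124 CPM in the compressed and 0.12 CPM in the control library.

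A gene was called higher or lower when it had a CPM of at least 1 in either library, a ratio of at least 2 or at most 0.5, and an interval that excluded 1. At these limits the interval requirement removed no gene. No p-value was computed, since genes are not replicates and edgeR's quasi-likelihood test has no residual degrees of freedom with 1 library per group. Long noncoding RNAs (lncRNAs) were taken from the gene type of the deposited table. For 29 gene lists fixed before the data were examined, the median log2 ratio of the members above the CPM minimum was set among 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile describes these libraries and is not a test. A list was described as standing apart at a percentile of at least 97.5 or at most 2.5.

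The genes named were chosen by a rule also fixed beforehand. It took the 8 higher and 8 lower mRNAs and the 5 higher and 5 lower lncRNAs whose interval limit nearest to no change was farthest from it. It also took up to 4 members of each list, the 2 highest and the 2 lowest ratios. Ibsp, Bglap, Runx2, Sp7, Alpl, Spp1, Tnfsf11, Tnfrsf11b, Ptgs2 and Il6 were always reported, with 5 noncoding RNAs recalled from the published study, namely Prkcz2, Hklos, Trp53cor1, Gdap10 and Ak3l2-ps. Some genes that the rule selects are not reported here. Any other gene is said to have been chosen after its values were seen. Older symbols were matched through a RefSeq gene table of the GRCm38.p6 assembly, which matched 39613 of the 44792 symbols (88.4%) and also gave gene positions, counted from 1. Positions of genes below are on GRCm38.

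The calling rule was tested on simulated libraries with the real gene means and depths and 200 changed genes. With counting error alone it called 55 of 100 genes of true fold 2, all 100 genes of true fold 3 and 27 of 13673 unchanged genes. With a biological coefficient of variation of 0.2 between cultures it called 59 of 100, 94 of 100 and 400 of 13727, and 37.3% of the intervals of unchanged genes held the true ratio. With a coefficient of 0.1, it called 64 of 13680 unchanged genes and 55.2% of their intervals held the true ratio. The log2 ratios of 10085 mRNAs with a mean CPM of at least 5 had a robust standard deviation of 0.26, which allows a coefficient of at most 0.121 for most of these mRNAs. The value of 0.121 also does not bound weakly expressed genes, or gene sets that vary more between cultures.

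Alternatives set beforehand were total-count scaling, size factors from DESeq2 1.42.0, upper-quartile factors, a loess fit of the ratio on mean abundance, no CPM minimum, a CPM minimum of 5, a prior count of 5, no interval requirement, intervals widened for an assumed coefficient of variation of 0.1 or 0.2, and fold limits of 1.5 and 4. Scaling with ribosomal RNA genes left out was added after seeing the data. Other computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6.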

Results

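RNA sequencing counts were compared between OCCM-30 cementoblast-like cells under compressive force and control OCCM-30 cells, with 1 library in each group. The title of the series names the lncRNA profile of cementoblasts under compression as its subject, and the design sets the compressed against the control transcriptome. Depth was similar, at 24296292 counts in the compressed and 25049919 counts in the control library, with 21227 and 20945 genes detected. The 10 most abundant genes held 6.04% of counts in the compressed and 5.58% in the control library. Every ratio below is of the compressed over the control library, has no replicate check, and carries an interval for counting error only. These values compare the libraries and not the conditions.

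The question of the first comparison was which genes differed in abundance under compression. The compressed library held more transcripts of genes that act under low oxygen and in glucose use, while most of the transcriptome lay close to a ratio of 1. Of 14001 genes above the CPM minimum, 429 were called higher and 130 lower, and 96% lay within 2-fold. Stanniocalcin 1 (Stc1), a secreted glycoprotein hormone, had 881 counts against 57, a 15.8-fold ratio (95% counting interval 12.2 to 21.2). Cyclin G2 (Ccng2), an atypical cyclin linked to cell cycle arrest, was 9.65-fold higher (8.59 to 10.9), with 2848 counts against 304. At a CPM minimum of 5 the calls numbered 154 higher and 12 lower, so most calls in both directions were of weakly expressed genes.

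**Figure D1:**
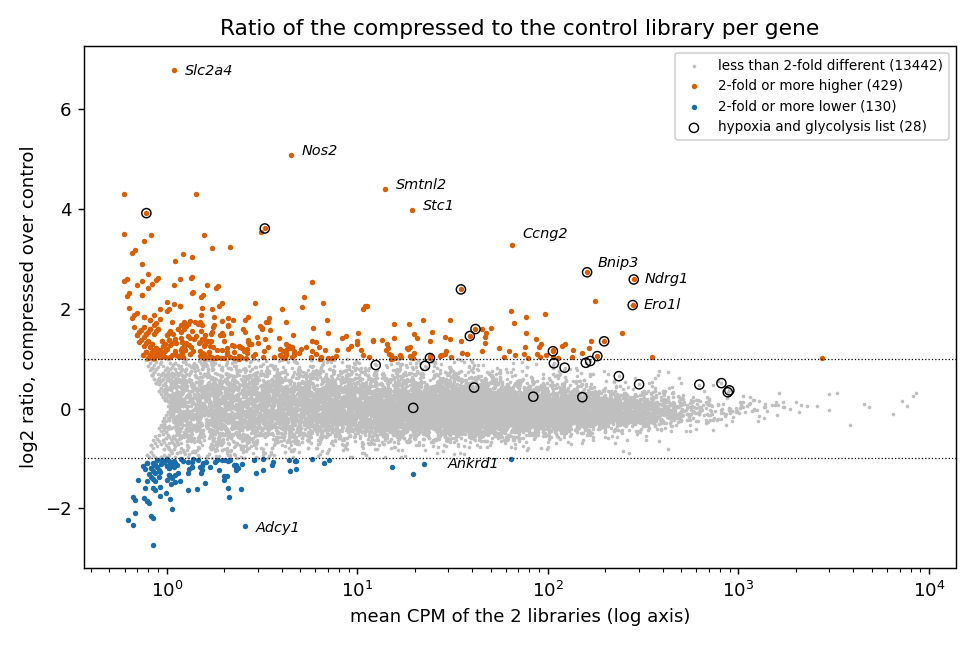
Each point is a gene above the CPM minimum, with the mean CPM of the 2 libraries on a log axis and the log2 ratio of the compressed over the control library on the vertical axis. Orange points are the 429 genes called higher, blue points the 130 called lower, and open circles the 28 members of the hypoxia and glycolysis list, all of which lie above 0; Slc2a4, with 0 control counts, is drawn at its ratio with the prior count.

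The other leading mRNAs among the higher genes included a pair of glucose transporters. Slc2a3, the neuronal-type glucose transporter, was 11.6-fold higher (6.68 to 23.9), on chromosome 6 at 122727809 to 122802363. Slc2a4, the insulin-responsive glucose transporter, had 53 counts against 0 and was at least 18.2-fold higher over a floor of 3 counts, while the lower limit of its counting interval was 14.3. Nos2, the inducible nitric oxide synthase, had 212 counts against 6, a ratio of 33.7 (16.5 to 100.5). Smtnl2, a smoothelin-like gene, was 21.2-fold higher (15.0 to 31.9). Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1, had 66 counts against 3, and its ratio of 19.6 had an interval of 7.44 to 113. Ankrd37, an ankyrin repeat gene induced by hypoxia, was 12.2-fold higher (7.02 to 25.02).

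Genes lower in the compressed library had smaller ratios. S100a7a, an S100 calcium-binding protein, was 2.48 times lower (2.16 to 2.87), with 274 counts against 703. Panx3, a pannexin channel of skeletal cells, was 2.26 times lower (1.93 to 2.66). Ptchd4, a patched-domain gene, was 2.17 times lower (1.91 to 2.47). A630033H20Rik had 1035 counts against 2148, 2.01 times lower (1.87 to 2.17). Adcy1, an adenylyl cyclase, was 5.13 times lower (3.23 to 8.91) with 20 counts against 108. Estrogen receptor alpha (Esr1) had 29 counts against 93, the neuropeptide Y receptor Npy1r 10 against 43, and the mitochondrial carrier Slc25a29 7 against 34, and all 3 were called lower.

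In the hypoxia response and glycolysis list, all 28 members above the CPM minimum had ratios above 1, 27 of them with intervals above 1, and 12 were called higher and 0 lower. The median log2 ratio was 0.91, above all 10000 matched random lists, whose highest median was 0.19. Car9, a carbonic anhydrase of hypoxic cells, had 36 counts against 2, a ratio of 15.1 with an interval of 4.78 to 159. At the other end, the glycolytic enzyme Pgk1 had a ratio of 1.17 (1.12 to 1.22) and Pfkfb4, a regulator of glycolysis, a ratio of 1.01 (0.888 to 1.15).

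Abundant members of the same list, chosen after their values were seen, had narrow intervals. Bnip3, a mitophagy receptor, was 6.63-fold higher (6.22 to 7.08), from 1054 control counts to 6775 in the compressed library. Ndrg1 was 5.999-fold higher (5.72 to 6.29), and the Myc antagonist Mxi1 5.23-fold higher (4.60 to 5.97). Ero1l, an oxidase of the endoplasmic reticulum, was 4.20-fold higher (4.03 to 4.39). Pdk1, a kinase that inhibits pyruvate dehydrogenase, was 3.01-fold higher, the glucose transporter Slc2a1 2.74-fold and the histone demethylase Kdm3a 2.54-fold. Vegfa, the vascular growth factor, was below the fold limit at 1.93 (1.85 to 2.02).

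Members of other stress and signalling lists differed in the same libraries. Immediate early genes, which respond within minutes to many stimuli, had 6 of 19 members called higher and 0 lower. Their median log2 ratio was 0.72, above all matched random lists, and was 0.41 at a CPM minimum of 5. Nr4a3, an orphan nuclear receptor, had 29 counts against 3, and Ier3 was 3.04-fold higher (2.78 to 3.34). Jun stood at a ratio of 1.03 (0.923 to 1.16) and Myc at 0.653 (0.582 to 0.731). Interferon-stimulated genes had a median log2 ratio of 0.67, at the 99.99th percentile of random lists, or 0.42 at a CPM minimum of 5. Of those 13 members 1 was called higher, Rsad2, with 33 counts against 11, while Irf7 had a ratio of 1.99 (1.55 to 2.59), and the interval of Irf1 included 1.

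Differentiation and mineralized matrix genes of cementoblasts and osteoblasts had a median log2 ratio of 0.05 at the 74.7th percentile of random lists. Of the 22 listed genes, 15 lay above the CPM minimum, and of these 1 was called higher and 0 lower. That gene was Phospho1, a phosphatase that starts mineral formation in matrix vesicles, 2.16-fold higher (1.89 to 2.49). Runx2, the osteoblast transcription factor, had a ratio of 0.787 (0.757 to 0.819). Sp7 had 99 counts against 98, the alkaline phosphatase gene Alpl 859 against 817, and osteopontin (Spp1) 4769 against 4460. Ank, a pyrophosphate transporter, had a ratio of 1.25 (0.937 to 1.68). Bone sialoprotein (Ibsp), a usual cementoblast marker, had 0 counts in both libraries, which allows up to 0.124 CPM in the compressed and 0.12 CPM in the control library. Osteocalcin (Bglap) had 12 counts against 11, below the CPM minimum, and a difference was not detectable at these counts. The related gene Bglap2, also on chromosome 3 and chosen after its values were seen, had 0 counts against 4. The treatment of reads that align to both genes is not given, so their low counts are uncertain. Dmp1, with 24 counts against 14, and Mepe and Sost, with 0 in both libraries, were chosen after their values were seen. Like Ibsp, Bglap and Bglap2, they are left out of the list median.

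Regulators of osteoclasts and inflammatory mediators included Nos2, the member called higher among 15, and 0 members called lower. The list median log2 ratio was 0.07, at the 71.9th percentile of random lists. RANKL (Tnfsf11), the cytokine that drives osteoclast formation, had 93 counts against 97, and its decoy receptor osteoprotegerin (Tnfrsf11b) 461 against 420. Cyclooxygenase 2 (Ptgs2), which makes prostaglandin precursors, had 2248 counts against 2255, a ratio of 1.03 (0.970 to 1.09). The chemokine Cxcl12 had a ratio of 0.607 (0.565 to 0.652) and Cxcl5 of 0.544 (0.314 to 0.900). Ccl5 had a ratio of 1.69 with an interval of 0.990 to 2.997. Interleukin 6 (Il6) had 5 counts against 23, a ratio of 0.242 (0.0666 to 0.603), and lay below the CPM minimum in both libraries.

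Targets and sensors of mechanical signals had no member called. YAP and SRF targets had a median log2 ratio of -0.15 over 15 members, at the 4th percentile of random lists. Ankrd1 had a ratio of 0.536 (0.476 to 0.601) and Cyr61 of 0.648 (0.618 to 0.678), while Acta2, smooth muscle actin, had 1.11 (1.08 to 1.14) and Actg2 1.482 (0.889 to 2.53). Mechanosensors and adhesion genes had a median of -0.10 over 12 members, with integrin beta 3 (Itgb3) at 1.37 (1.25 to 1.51), Itga5 at 1.11, connexin 43 (Gja1) at 0.798 (0.764 to 0.833) and Cav1 at 0.850. BMP and TGF-beta signalling genes had 0 of 13 members called and a median of -0.22, at the 1.68th percentile. Its lowest members were the BMP targets Id3, with a ratio of 0.535 (0.484 to 0.590), and Id2, with 0.591 (0.534 to 0.653). Its highest were Hey1 at 1.71 (1.12 to 2.68) and Tgfb1 at 1.29 (1.22 to 1.35). Wnt targets and inhibitors had a median of 0.01 over 9 members, with Tcf7 at 1.29, Lef1 at 1.26, Wisp1 at 0.706 and Axin2 at 0.600 (0.442 to 0.804).

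**Figure D2:**
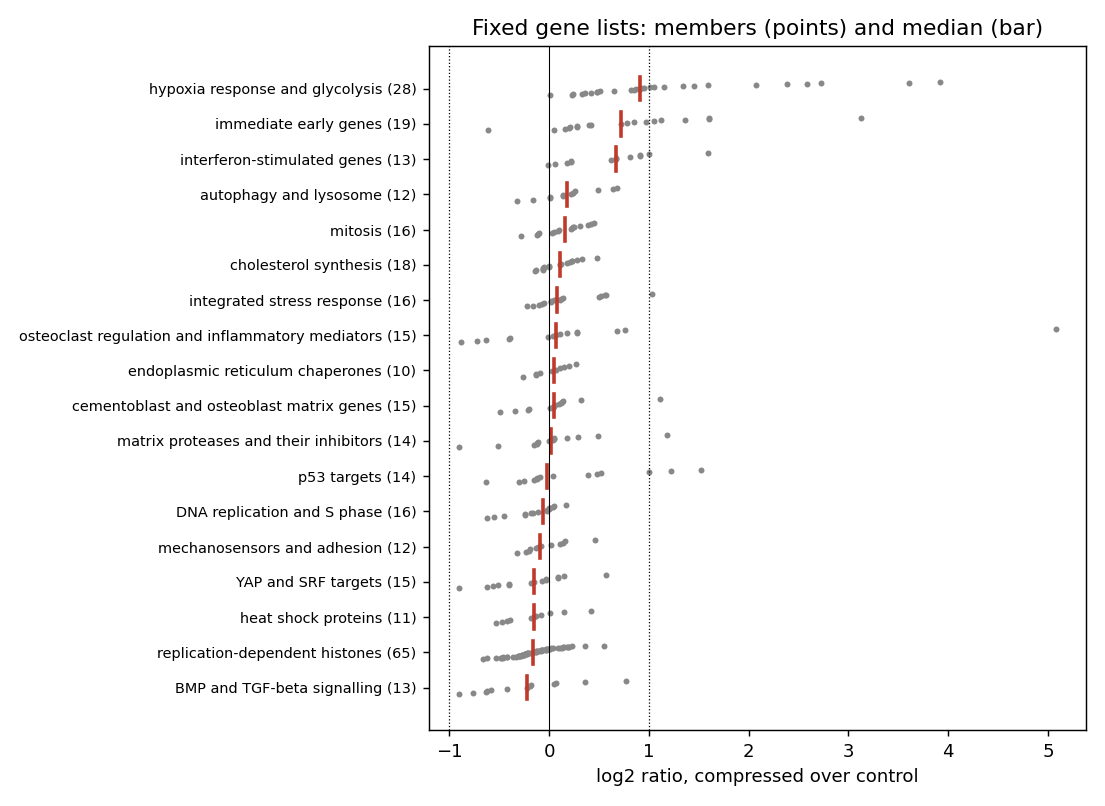
Log2 ratios of the compressed over the control library for the members (grey points) of 18 fixed gene lists, with the list median as a red bar and the number of members above the CPM minimum in parentheses. The hypoxia and glycolysis list has its median at 0.91, immediate early genes at 0.72 and interferon-stimulated genes at 0.67, and the other lists shown have medians between -0.22 and 0.18; dotted lines mark the 2-fold limits.

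Growth, arrest and protein quality lists had few calls. Among 14 p53 targets 2 were called higher, the cell cycle inhibitor Cdkn1a at 2.87-fold (2.67 to 3.09) and the apoptosis gene Bbc3 at 2.34-fold (1.80 to 3.09). Phlda3 and Aen, with ratios of 0.809 and 0.644, were the lowest, and the list median was -0.02. Mitosis genes had a median log2 ratio of 0.16, at the 99.8th percentile, with 0 of 16 called. Aurkb had a ratio of 1.37, Cenpf 1.34, Cdk1 0.920 and Ccnb1 0.822. DNA replication genes had a median of -0.07 and 0 of 16 called, with Ccne1 at 0.649, Rrm2 at 0.683, E2f1 at 1.12 and Cdt1 at 1.03. Integrated stress response genes had a median of 0.08 and 1 of 16 called higher, the lipoprotein receptor Vldlr at 2.04-fold (1.94 to 2.15), with Chac1 at 1.49, Psat1 at 0.894 and Mthfd2 at 0.855. Endoplasmic reticulum chaperones (Herpud1 1.20, Dnajb9 1.15, Hyou1 0.916, Sdf2l1 0.831) had a median of 0.05 with 0 of 10 called. Heat shock proteins had a median of -0.15 with 0 of 11 called, from Dnaja1 at a ratio of 0.691 and Hsph1 at 0.722 to Hspb1 at 1.11 and Hspa1a at 1.34.

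In metabolic and matrix turnover lists, autophagy and lysosome genes had a median log2 ratio of 0.18, at the 99.4th percentile, and 0 of 12 were called. Wipi1 had a ratio of 1.60 and Ulk1 of 1.56, against 0.895 for Becn1 and 0.799 for Atg5. Cholesterol synthesis genes stood at the 99.0th percentile with a median of 0.11 and 0 of 18 called, with Stard4 at 1.40 and Insig1 at 1.25 the highest. NRF2 targets had a median of -0.12 and 0 of 9 called, from Txnrd1 at 0.680 and Gclm at 0.874 to Me1 at 1.24 and Hmox1 at 1.77 (1.66 to 1.89). Matrix proteases and their inhibitors had a median log2 ratio of 0.02, with 1 of 14 called higher and 0 lower. The aggrecanase Adamts5 had a ratio of 0.536 (0.517 to 0.556), and Mmp13 at 1.40 and Mmp9 at 0.699 had intervals that included 1.

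Ribosomal protein, histone and mitochondrial lists also had no member called, and many of these genes have near-identical copies. The 76 ribosomal protein genes had a median log2 ratio of -0.05, at percentile 18.1, with the lowest values for Rps12 at -0.65 and Rps29 at -0.64, while Rpl29 had 0.35. The 65 histone genes had a median of -0.16, at percentile 0.02, from Hist1h2br at -0.66 and Hist1h2aj at -0.63 to Hist1h1e at 0.36 and Hist1h4n at 0.55. The 12 mitochondrially encoded mRNAs had a median of 0.07, with COX1 at 0.31, ND5 at 0.24, ND2 at -0.17 and ND1 at -0.24.

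Markers of other cell types had no member called. Macrophage and osteoclast markers had 4 of 10 genes above the CPM minimum, Cd68, Csf1r, Cd14 and Ctsk, with a median log2 ratio of -0.14 and intervals that all included 1. The highest was Cd14, at 9.96 CPM in the compressed and 11.01 CPM in the control library. Krt8 was the epithelial marker above the minimum, with 27 counts against 23. Endothelial markers above it were Vwf, with 84 counts against 70, and Pecam1, with 21 against 32. Periodontal ligament and fibroblast markers had a median of 0.05 over 6 members, with fibronectin (Fn1) at a ratio of 1.24, Dcn at 1.75 (1.21 to 2.57), S100a4 at 0.948 and Aspn at 0.705. Of the chondrocyte and adipocyte markers, Col2a1 had a ratio of 1.12 and Sox9 of 0.804, with a median log2 ratio of -0.07.

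The second comparison addressed the noncoding transcripts that the series title names. Of 9882 lncRNA rows, 918 passed the CPM minimum, and 72 were called higher and 31 lower. That was 7.84% and 3.38% of the lncRNAs, against 2.49% and 0.51% of the 11757 mRNAs. With the loess fit 53 lncRNAs were called higher and 44 lower, so the excess of higher over lower lncRNAs was smaller. Most called lncRNAs lay below 5 CPM in both libraries, where counting error is large, and these shares were not compared at matched expression. At a CPM minimum of 5, 4 lncRNAs were called higher and 0 lower. These 4 were Trp53cor1, Gdap10, Gm15850 and LOC102636048, the last 2 chosen after their values were seen, with ratios of 2.56 (1.98 to 3.37) and 2.11 (1.60 to 2.83).

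Leading lncRNAs among the higher genes had few control counts. LOC102632005, matched to no position here, had 95 counts against 10, a 9.39-fold ratio (5.10 to 21.1). LOC102640584 had 59 counts against 7, an 8.19-fold ratio (3.97 to 22.6), and lies on chromosome 11 at 62933253 to 62939590. LOC102632091, on chromosome 17 at 72871327 to 72896256, had 32 counts against 4, and LOC102639512 had 34 against 5. 9530026P05Rik, on chromosome 6 at 92940582 to 93111749, had 115 counts against 27, a 4.33-fold ratio (2.87 to 6.95). Its span overlaps that of Adamts9, which had a log2 ratio of 0.89, so the counts of this pair are uncertain.

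Ranked by the interval limit nearest to no change, the leading lower lncRNAs were LOC102638178 and LOC381967, both with few counts in the compressed library. LOC102638178, on chromosome 18 at 5956746 to 5966908, had 5 counts against 37 and was 6.61 times lower (2.81 to 23.4). LOC381967, on chromosome 7 at 99260481 to 99267218, had 7 against 35. The gene 5430421F17Rik, on chromosome 8 at 25302650 to 25306270, had 25 counts against 79 and was 3.02 times lower (1.93 to 5.01). LOC102634847 had 5 counts against 26, and Gm10785 had 6 against 28. LOC381967 overlaps Map6 and Gm10785 overlaps Donson and Cryzl1, genes with log2 ratios between -0.23 and 0.02.

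Among the noncoding RNAs recalled from the published study, 4 had a row and were called higher, with a median log2 ratio of 1.73. How the study chose them is not given in the sources used here, so they are not taken as independent of these libraries. Trp53cor1, also called lincRNA-p21, lies on chromosome 17 at 29057474 to 29079126, upstream of Cdkn1a, and was 2.78-fold higher (2.07 to 3.81). Gdap10, on chromosome 12 at 32824116 to 32826919 within the span of Nampt, was 2.24-fold higher (1.86 to 2.72). Ak3l2-ps, a pseudogene in RefSeq on chromosome 2 at 72633848 to 72635500, had 156 counts against 40, a 3.99-fold ratio (2.83 to 5.85). Prkcz2, also a RefSeq pseudogene, on chromosome 7 at 27882399 to 27884621, had 35 counts against 6, a 5.64-fold ratio (2.51 to 17.5). Its span overlaps Zfp607a, which had a log2 ratio of -0.23. Hklos was not analysed here under that spelling. Hk1os, chosen after its values were seen, overlaps Hk1 on chromosome 10 at 62340234 to 62363611 and was 4.85-fold higher (2.72 to 9.91). Counts of pseudogenes and overlapping genes are uncertain.

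**Figure D3:**
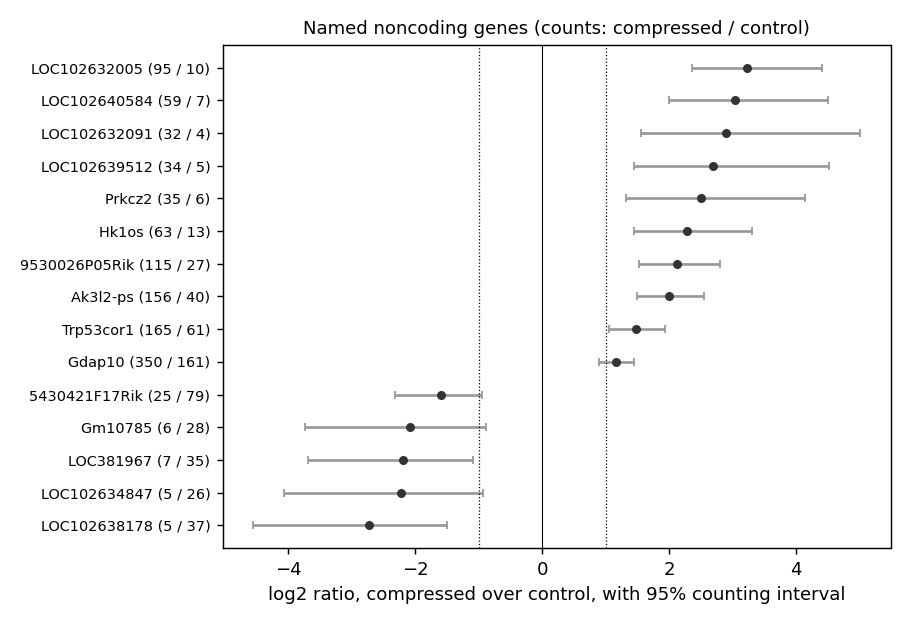
Log2 ratios of the compressed over the control library for 15 noncoding genes named in the text, with 95% counting intervals as bars and the compressed and control counts in parentheses. Ratios run from -2.72 for LOC102638178 to 3.23 for LOC102632005, and dotted lines mark the 2-fold limits.

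A fixed list of 27 well-known lncRNAs had 19 members above the CPM minimum. Their median log2 ratio was -0.23, at percentile 0.1 of matched random lists, with 0 of 19 called. All 918 lncRNAs above the minimum had a median of 0.06. The median of the list was -0.14 with no CPM minimum. Neat1, the scaffold of nuclear paraspeckles, had a ratio of 1.44 (1.39 to 1.481) and 0610007N19Rik, now named Snhg18, of 1.29 (1.15 to 1.45). Snhg4 and Gm11974, now named Snhg15, both from the family that hosts small nucleolar RNAs (snoRNAs), had ratios of 0.611 (0.465 to 0.795) and 0.537 (0.426 to 0.673). Among other noncoding classes, 0 of 91 snoRNAs were called higher and 7 lower, with a median log2 ratio of -0.27. Of 71 rows typed as miRNA above the CPM minimum, 8 (11.3%) were called higher and 1 (1.41%) lower, with a median of 0.07. Of all genes above the minimum, 3.06% were called higher and 0.93% lower. The 34 precursor miRNA rows had 4 called higher and 3 lower, with a median of -0.01. The libraries were not described as short RNA libraries, so these rows are not taken as levels of mature miRNAs. Ribosomal RNA genes took 0.51% of counts in the compressed and 0.321% in the control library, mainly through Rn18s-rs5, a copy of the 18S ribosomal RNA, with 0.365% against 0.181%.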

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

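With 1 library per group, neither leaving out a replicate nor splitting the samples was possible. No paired analysis was possible because each group has 1 sample. Calls numbered 429 higher and 130 lower in all, with 72 and 31 among lncRNAs. With no CPM minimum they became 774, 369, 196 and 81, since 22774 genes were then compared, and with a CPM minimum of 5 they became 154, 12, 4 and 0 because 11008 genes remained. A fold limit of 1.5 gave 1023, 519, 122 and 90, and a limit of 4 gave 67, 8, 11 and 4, by construction. A prior count of 5 gave 78 lower genes and 17 lower lncRNAs, as it pulls ratios of low counts toward 1. Under all other alternatives these counts stayed within 1.5 times, including loess with 362 and 177 and an assumed coefficient of variation of 0.2 with 381 and 96. For lncRNAs loess gave 53 higher and 44 lower calls, against 72 and 31. No named gene that was called changed direction. The medians of p53 targets (-0.04 to 0.001), matrix proteases (-0.003 to 0.04) and Wnt genes (-0.11 to 0.19) changed sign between settings. Of 39 named genes that were called, 38 remained with upper-quartile factors and 38 with loess, 19 at a CPM minimum of 5, 23 at a fold limit of 4, and 39 under each other setting. The hypoxia and glycolysis median log2 ratio ranged from 0.90 to 0.94; clock, ribosome biogenesis and snoRNA medians kept their sign under each scaling, and the all-gene median stayed between -0.02 and 0.02. Depth limits weakly expressed genes, and 4 of the 72 lncRNAs called higher remained at a CPM minimum of 5.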

Other observations

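The tests of explanations and the gene lists in this part were chosen after the results were seen, and no spread between cultures could be measured. Circadian clock genes, a list chosen after seeing the data, had 5 of 13 members called higher and 0 lower. The median log2 ratio was 0.94, above all 10000 matched random lists. That rank lends no support, since the list was chosen after seeing the data. The repressors Bhlhe40 and Bhlhe41 were higher by log2 ratios of 1.88 and 1.36, the nuclear receptor gene Nr1d1 by 1.78 and the period gene Per1 by 1.22. Gm129, also named Ciart, had 1.05, while Clock had -0.29, Cry1 -0.28 and Arntl -0.08. Notch3, a Notch receptor, had 2923 counts against 852, a log2 ratio of 1.82. Its pathway list had a median of -0.01, with 5 of 10 members above 1, such as Hey1 at 0.77 and Notch1 at 0.41, and 5 below 1, such as Jag1 at -0.51 and Lfng at -0.74.

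Ribosome biogenesis factors, also listed after seeing the data, had ratios below 1 for all 22 members and intervals below 1 for 21. The median log2 ratio was -0.47, below all matched random lists, and 0 members passed the 2-fold limit. As for the clock list, that rank lends no support. Nop2, a methyltransferase of ribosomal RNA, had -0.70, Nop56 -0.66, Polr1b, a subunit of RNA polymerase I, -0.60, and nucleolin (Ncl) -0.46. Myc, which activates many of these genes, had -0.62. Mitochondrial mRNAs were counted unevenly, with 229424 and 190932 counts for COX1 but 218 and 220 for COX2, 225 and 253 for COX3, and 163 and 153 for ATP6. Gapdh had 55.5 CPM in the compressed and 30.2 CPM in the control library, while its pathway neighbour Tpi1 had 955 and 672 CPM. Levels of mitochondrial genes and Gapdh, which have near-identical copies in the nuclear genome, are uncertain because the treatment of reads with several alignments is not given.

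The higher hypoxia response and glycolysis genes were set against technical explanations. The lowest list median over 5 other scalings was 0.90. These scalings differed little, with all-gene medians from -0.02 (DESeq2) to 0.001 (upper quartile), so they could hardly have moved the list. A scaling error would shift matched random lists as well, yet their highest median was 0.19 against 0.91 for this list. That difference argues against scaling as the cause. Counting error is also argued against, since 27 of 28 members had intervals above 1. A difference between the cultures other than the force, such as density, medium volume or oxygen supply, cannot be told apart from the force with 1 library per group. The force itself also stays open and was not tested apart from such differences.

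Several noncoding genes had nearly the ratio of a coding relative or neighbour. The log2 ratio of Ak3l2-ps differed from that of Ak4, with 2475 counts against 655, by 0.033 (-0.48 to 0.55). That of Gdap10 differed from that of Nampt by -0.065 (-0.56 to 0.43). Gdap10 had more counts, 350 against 161, than Nampt, with 155 against 68. Reads of Ak4 counted for Ak3l2-ps, or reads shared in either direction between Gdap10 and Nampt, may give such ratios. Shared regulation would give the same. Hk1os lay above Hk1 by 1.73 (0.88 to 2.58), so its counts did not follow those of Hk1 as a whole. Reads from a part of Hk1 stay open as its source, since Hk1os lies within the span of Hk1 and the strand setting is not given. Trp53cor1 and Cdkn1a, 11853 bases apart, differed by -0.05 (-0.48 to 0.39), and Prkcz2 and Prkcz, with 8 and 4 counts for Prkcz, by 1.53 (-0.51 to 3.57). A comparison of all called lncRNAs with their neighbours was void, since 77.7% had a position and 80% was needed.

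The lower snoRNAs, with a median log2 ratio of -0.27 (bootstrap interval over genes -0.38 to -0.15) and 69 of 91 below 1, were examined for a loss of short RNAs. The other 31 short structural RNAs had a median of 0.10 (-0.09 to 0.31), or 0.02 (-0.10 to 0.27) with loess, where snoRNAs had -0.36. They lay above the snoRNAs by 0.37 (0.15 to 0.59), and by 0.38 (0.18 to 0.65) with loess. That argues against an equal loss of all short RNAs as the whole cause. A smaller loss, or one that depends on length, stays open, since these RNAs were not matched to the snoRNAs on length. Of the 91 snoRNAs, 85 lay within 63 host genes, whose median of -0.15 stood at percentile 0.08 of matched random lists, with 0 hosts called lower. That rank lends no support, since the hosts were taken after the lower snoRNAs were seen and include ribosome biogenesis factors such as Nop56 and Ncl. Hosts had ratios below 1 for 47 of 65 snoRNAs below 1, and for 13 of 20 snoRNAs at or above 1. Lower host transcripts stay open as an explanation, since the median difference of snoRNA minus host was -0.09 (-0.21 to 0.003), while across the pairs, which are not independent replicates, the rank correlation was 0.14 (-0.08 to 0.36).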
